A study of Mus musculus with 60 samples.

How the data were processed

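RNA was sequenced in 60 mouse libraries in 3 experiments. Experiment 1 has 36 libraries in 12 groups of 3: B9 cells (an immortalized brown preadipocyte line), pBAT and pWAT cells (primary preadipocytes of newborn pups) at days 0, 2, 4 and 6 of differentiation. Experiment 2 has 16 libraries in 4 groups of 4: pBAT cells given Vehicle, SA at 1 mM, HA at 10 µM, or both. Experiment 3 has 8 libraries of brown fat from female mice in 2 groups of 4, BAKO and WT, each from its own animal. Per the labels, RNA was isolated with TRIzol, experiments 1 and 2 used stranded mRNA libraries made by BGI, and experiment 3 used poly-T beads at Novogene.

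The deposited files hold 5 tables of gene values: 1 for each cell type of experiment 1, and 1 each for experiments 2 and 3. The submitters' processing notes name kallisto, DESeq2 and the genome build GRCm39, with versions not given in the sources used here. Although the files are named as raw counts, the values deposited by the authors are on a log2 scale: they run from -1.96 to 21.28, none is a whole number, and 2 raised to the values sums to 18.0 to 29.9 M per library. The base 2 rests on these sums, since the sources used here do not state it. Genes with low values vary little on this scale. In experiment 2 the median SD over all libraries was 0.00841 for genes with a mean under 1 and 0.114 for genes with a mean of at least 9. Fold changes of low genes are therefore understated, as under a regularized log. Read depth per library is unknown from these values, so no detection limit or counting error is given. Each table was normalized on its own, so tests were made within a table only.

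Gene symbols came from the GENCODE M21 names on GRCm38, which matched 99.63 to 99.77% of the gene identifiers, and no coordinates were used. The files hold 18746 to 20180 genes. A gene was tested in a table if its highest group mean was at least 4, leaving 12462 to 13497 genes. The design fixed beforehand called for a count model. Log2 values do not suit it, so limma 3.58.1 in R 4.3.3 was used on the values as deposited: a linear model with 1 mean per group over all libraries of a table, moderated t tests with a mean-variance trend, Benjamini-Hochberg adjustment over the genes tested and a call at adjusted p under 0.05. Confidence intervals (CI) are 95%. There were 16 comparisons: days 2, 4 and 6 against day 0 in each cell type, 5 pairs of treatments and their interaction in experiment 2, and BAKO against WT. Group SDs are between libraries.

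The planned pBAT against pWAT comparisons at day 0, at day 6 and as day 6 minus day 0, and B9 against pBAT as day 6 minus day 0, were not run, because the cell types were normalized in separate tables. The numbers in the library names were not taken as pairs.

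Before the values were seen, 36 gene lists were fixed (pathways, complexes and cell type markers). Lists with at least 4 tested genes were tested with camera of limma, with a preset correlation between genes of 0.01 and, as an alternative, with a correlation estimated from the residuals. Adjustment was over the lists of a comparison. For each list the genes called over all genes are counted, and also those called when the p-values were adjusted over the list alone. With the estimated correlation SA against Vehicle had 3 of 34 lists called, BAKO against WT 0 of 36 and the interaction 0 of 34, against 17, 20 and 23 with the preset one.

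Genes were named by a rule fixed before the files were opened. It takes the heme synthesis genes and Ucp1, then the 6 largest rises and 6 largest falls among called genes. For the latter, predicted and clone names were left out, the mean over both groups had to be at least 5 CPM, and all libraries of one group had to lie above all of the other (for interactions only the call and the mean were needed). CPM was computed from 2 raised to the value, scaled by the sum of these over the library. Of each list described, up to 4 genes with the smallest adjusted p were named, and Alas1 is given in every BAKO and WT library. Not all of these genes are printed, and 1 gene that the rule names is not reported here.

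For heme add-back, genes were called and chosen with 2 of the 4 SA libraries against Vehicle and the change from the other 2 SA libraries to HASA was measured, for all 6 choices. SA and BAKO changes were compared over all genes tested in both and over genes of at least 10 CPM in both. The 200 genes with the largest changes in SA were tested in BAKO with camera.

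The alternatives fixed beforehand were no filter on low values, a fit of only the 2 groups compared, the replicate number as a block, removal of mitochondrially encoded genes (their rows only), each library left out in turn and the estimated correlation. Alternatives chosen after seeing the data were limma without the trend, median centring, quantile normalization, a stricter filter (highest group mean of at least 6), BAKO against WT without BAKO 3 and BAKO 5, and skeletal muscle or macrophage list means as covariates. The intended DESeq2 size factors and DESeq2 test need counts and were not run. Leaving a library out could not redo the authors' log transform. Each count was also compared with the counts from other splits of the same libraries into 2 groups. No 2 libraries of a group were duplicates: no values were equal between libraries of a group and the root mean square difference was 0.118 to 0.464.

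The fit was tested on simulated data with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. Residuals were drawn independently for each gene, and all other genes were left unchanged. The shares below hold for that setting. They may not carry over to the real tables, where genes vary together and many more genes can change. For BAKO against WT (13497 genes), 52% and 87% were recovered, with 4.14% of calls false. For SA against Vehicle (12799 genes) the shares were 95%, 100% and 5.80%, and for pBAT day 6 against day 0 (13144 genes) 47%, 89% and 6.85%. The highest false share was 8.28%, for pWAT day 4 against day 0 (13057 genes), with 45% and 88% recovered, followed by 7.98% for B9 day 2 and 7.50% for B9 day 4 (12462 genes), and the lowest was 2.96%, for HASA against Vehicle.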

Results

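Heme synthesis genes, branched-chain amino acid (BCAA) catabolism genes and thermogenic genes were followed in 3 settings. Experiment 1 took B9 brown preadipocytes, primary brown preadipocytes (pBAT) and primary white preadipocytes (pWAT) through 6 days of differentiation. Experiment 2 gave pBAT adipocytes succinylacetone (SA), an inhibitor of heme synthesis, heme-arginate (HA), or both (HASA). Experiment 3 compared brown fat of mice lacking Alas1 in brown adipocytes (BAKO) with wild type (WT). Changes are differences of group means on the log2 scale with the standard error of the limma fit (SE), and group values are means ± SD of log2 values.

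In B9 cells, Alas1, the first enzyme of heme synthesis, rose from 10.25 ± 0.0929 at day 0 to 12.87 ± 0.11 at day 6, a change of 2.61 (SE 0.063, n = 3 per day, limma adjusted p = 3.6e-14). It had already risen by 1.35 at day 2 and 2.19 at day 4. Of the 8 heme synthesis genes tested, 7 were higher and 1 was lower at day 6, with a median change of 0.68. Alad rose by 1.18, Ppox by 1.41, Urod by 0.89 and Fech by 0.34, while Cpox was lower (change -1.02, adjusted p = 9.23e-09). The heme synthesis list had an adjusted p of 0.0438, and adjusted p = 0.112 with an estimated correlation between genes. Uros, higher by 0.47, lost its call after quantile normalization (0.081, adjusted p = 0.609).

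Ucp1, the uncoupling protein of brown fat mitochondria, rose in B9 by 5.56 at day 6 (7.76 ± 0.105 against 2.20 ± 0.00616, SE 0.209, adjusted p = 4.81e-12). Its changes at day 2 and day 4 were 0.82 and 0.66 (adjusted p = 0.00294 and 0.0108), and the day 4 call was lost without day 4 replicate 1 (0.498, adjusted p = 0.0572). Values at these 2 days (2.61 to 3.53) lay under the cut of 4 used to filter genes. Low values hardly vary on this scale, so an early rise of Ucp1 rests on weak ground. All 20 thermogenic and brown adipocyte genes tested were higher at day 6 (median 3.18, adjusted p = 4.97e-08), among them the potassium channel gene Kcnk3 (7.41), Cox7a1 (6.51) and the coactivator gene Ppargc1a (4.69). BCAA catabolism genes moved with them: 32 of 33 were higher and 1 was lower (median 1.72, adjusted p = 1.8e-09). Aldh6a1, an enzyme of valine breakdown, rose by 4.75 (SE 0.0766), Bckdha, a subunit of the branched-chain keto acid dehydrogenase, by 3.67, and the transaminase gene Bcat2 by 3.56. Aldh6a1 was already higher by 3.05 at day 2, when 28 of 33 BCAA genes were higher and 3 lower.

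The largest rises in B9 at day 6 were those of Gpd1 (10.34, SE 0.146), the lipid droplet gene Plin1 (9.79), the adipsin gene Cfd (9.34) and G0s2 (9.14). All 22 general adipocyte genes were higher (median 5.37, adjusted p = 2.62e-13), as were all 36 complex I genes (median 1.5, adjusted p = 4.32e-13, and adjusted p = 0.0572 with an estimated correlation). The largest falls were those of the smooth muscle actin gene Acta2 (-6.09, SE 0.0944), Tagln (-6.01), Ccn4 (-5.87) and the interleukin receptor gene Il1rl1 (-5.60). Of 21 cell cycle genes, 18 were lower and 2 were higher (median -0.62), with Birc5 at -1.43 and Ccna2 at -1.19. That list had an adjusted p of 0.000173, and adjusted p = 0.101 with an estimated correlation. All 14 circadian clock genes were higher (median 1.40, adjusted p = 7.64e-05), including Npas2 (3.00) and Per3 (2.42). At day 6 limma called 9874 of 12462 genes, 5044 higher and 4830 lower (51.1% higher, but 48.2% after median centring and 44.8% after quantile normalization). Day 2 and day 4 had 8618 and 9333 called genes, the largest rises being Agt at day 2 (8.28) and Gpd1 at day 4 (10.49).

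In pBAT cells Alas1 rose by 2.68 from day 0 to day 6 (9.99 ± 0.155 to 12.67 ± 0.242, SE 0.102, n = 3, limma adjusted p = 2.6e-12). Its highest day mean was at day 4, 3.19 above day 0. As in B9, 7 of 8 heme synthesis genes were higher at day 6 and Cpox was lower. Urod rose by 1.55, Alad by 1.35, Uros by 1.11, Fech by 0.87 and Ppox by 0.60. The list had a median change of 0.99 and an adjusted p of 0.00803, and adjusted p = 0.0609 with an estimated correlation. Cpox (-0.21, adjusted p = 0.0225) lost its call without day 0 replicate 2 (-0.184, adjusted p = 0.0778), day 0 replicate 4 (-0.206, 0.054), day 6 replicate 1 (-0.163, 0.0966) or day 6 replicate 4 (-0.196, 0.0603). At day 2 Cpox was higher by 0.26 (adjusted p = 0.00827), a call lost after median centring (0.177, adjusted p = 0.0567) or quantile normalization (0.175, 0.0588).

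Ucp1 rose in pBAT by 3.91 at day 6 (6.41 ± 0.518 against 2.50 ± 0.00599, SE 0.28, adjusted p = 5.22e-09). Of 21 thermogenic genes 19 were higher and 1 was lower (median 3.42, adjusted p = 5.44e-08), with Cox7a1 at 7.31, the beta-3 adrenergic receptor gene Adrb3 at 6.95 and Kcnk3 at 6.66. Among 33 BCAA catabolism genes 31 were higher and 2 lower (median 2.35, adjusted p = 4.16e-11), led by Acss3 (6.61), Aldh6a1 (4.86) and Bckdha (4.38). The largest single rises were Thrsp (9.27, SE 0.117), the retinol carrier gene Rbp4 (8.47) and the adipokine gene Retn (8.24), and the largest falls were Gjb2 (-5.80), Cnn1 (-5.70) and Actg2 (-5.44). Mup22 was higher by 8.11, but reads of this multigene family may be shared between near-identical members. All 21 cell cycle genes were lower at day 6 (median -2.69, adjusted p = 4.94e-10), Ccna2 by -3.29, although at day 2 the same list had 15 of 21 genes higher and none lower. The limma counts were 8738, 9655 and 10187 of 13144 genes at days 2, 4 and 6.

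Macrophage markers changed with differentiation in the primary pBAT cultures. At day 6, 12 of 14 were higher (median 2.28), with the mannose receptor gene Mrc1 at 3.10 and the complement gene C1qb at 2.63 (11.30 ± 0.203 against 8.67 ± 0.0503). The list had an adjusted p of 3.7e-05, and adjusted p = 0.137 with an estimated correlation. Smooth muscle and pericyte markers were lower (9 of 10, median -2.72, adjusted p = 7.33e-05). All 13 mitochondrially encoded genes were higher (median 1.55, adjusted p = 4.92e-05, and adjusted p = 0.23 with an estimated correlation), and their share of a library went from 3.26 to 3.87% at day 0 to 9.27 to 10.3% at day 6.

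In pWAT cells, too, Alas1 was higher at day 6 (11.92 ± 0.16 against 9.70 ± 0.078, change 2.22, SE 0.0898, n = 3, limma adjusted p = 1.74e-11). The heme synthesis list again had 7 of 8 genes higher and Cpox lower (-0.44), with Uros at 1.12, Urod at 1.00, Fech at 0.74 and Alad at 0.63. Its median was 0.69 and its adjusted p 0.0258, and adjusted p = 0.158 with an estimated correlation. Of the 33 BCAA catabolism genes 30 were higher and 1 lower (median 1.82, adjusted p = 4.44e-11), with Acss3 at 6.71, Aldh6a1 at 4.70 and Bckdha at 3.75. Ucp1 stayed below the filter on low values in pWAT and was not tested. Even so, 14 of the 16 thermogenic genes tested there were higher and 1 lower (median 2.58, adjusted p = 1.08e-05), with Adrb3 at 6.93, Kcnk3 at 5.96 and Cox7a1 at 4.77.

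Fatty acid synthesis genes were all higher in pWAT at day 6 (14 of 14, median 4.72, adjusted p = 5.26e-10, and adjusted p = 0.0624 with an estimated correlation). Thrsp (9.87), Rbp4 (8.42), Retn (8.36) and the carbonic anhydrase gene Car3 (8.24) had large rises, while Cnn1 (-5.92), Actg2 (-5.55), Ccn2 (-5.46) and Lrrc15 (-5.44) had the largest falls. All 21 cell cycle genes were lower (median -2.55, adjusted p = 2.54e-11). All 14 interferon response genes were higher (median 2.90, adjusted p = 4.96e-06, and adjusted p = 0.15 with an estimated correlation), with Rtp4 at 4.64, Oasl2 at 4.09 and Ifit3 at 4.06 (SE 0.204). Macrophage markers were higher as well, 13 of 14 (median 3.33, adjusted p = 6.79e-08, and adjusted p = 0.0557 with an estimated correlation), with Mrc1 at 4.80 and C1qb at 3.54. Called genes numbered 6876, 8577 and 9243 of 13057 at days 2, 4 and 6.

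The 3 cell types were normalized separately by the authors, so differences between them were not tested and their values stand side by side only. In B9 the column names of days 2, 4 and 6 carry a letter R that those of day 0 lack and the labels do not explain, so it is not known whether day 0 was handled apart from the later days. Labels of experiments 1 and 2 do not say that the replicates are separate cultures, so each p-value there measures only the spread between the samples. With 3 libraries per day, 10 splits of the libraries into 2 groups of 3 exist, too few for a share under 0.05.

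**Figure D1:**
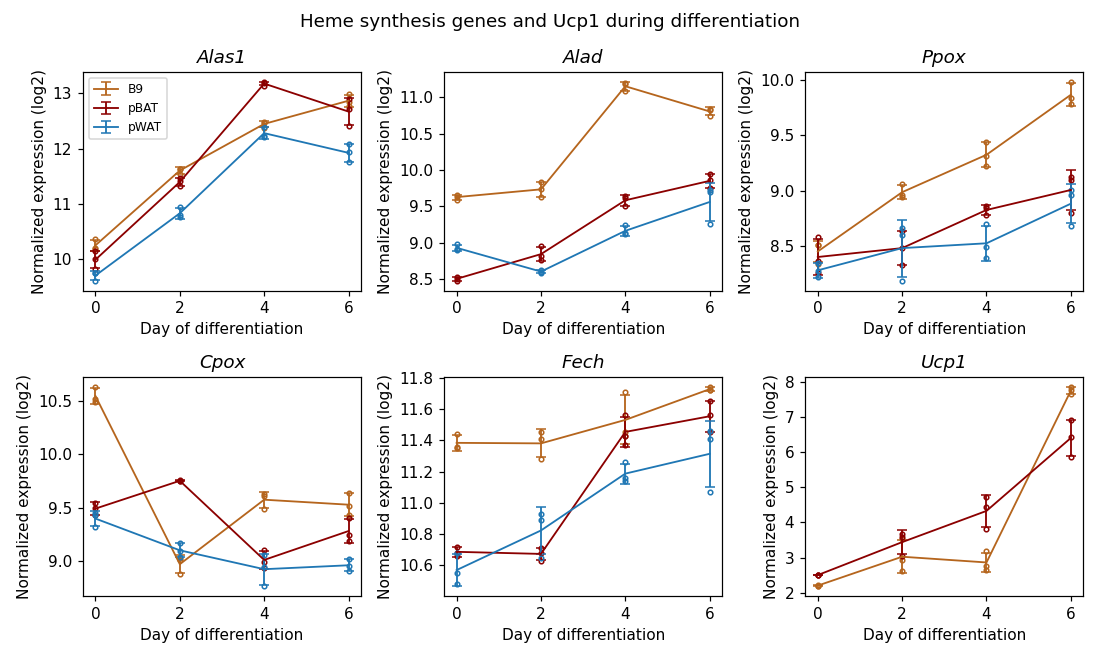
Log2 values of Alas1, Alad, Ppox, Cpox, Fech and Ucp1 over 6 days of differentiation in B9, pBAT and pWAT cells, with Ucp1 drawn for B9 and pBAT. Points are libraries (n = 3 per day), lines join day means and bars are SD; the 3 cell types were normalized separately.

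SA raised Alas1 in pBAT adipocytes 2.45-fold (13.72 ± 0.0691 against 12.42 ± 0.0596 in Vehicle, change 1.29, SE 0.0469, n = 4, limma adjusted p = 7.65e-13). The heme synthesis list did not pass as a whole: of 8 genes, Alas1 among them, 3 were higher and 2 lower (median 0.06, adjusted p = 0.405), with Alad at -0.18 and Ppox at -0.18. Cpox (0.18) was called at adjusted p = 0.0229. It lost its call without SA replicate 2 (0.135, adjusted p = 0.0856), SA replicate 4 (0.154, 0.0687) or Vehicle replicate 1 (0.135, 0.086).

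Ucp1 was 3.73-fold lower with SA (5.78 ± 0.0261 against 7.68 ± 0.235, change -1.90, SE 0.114, adjusted p = 5.35e-10). The thermogenic and brown adipocyte list had 13 of 20 genes lower and 1 higher (median -0.27, adjusted p = 5.06e-05). Cidea, a lipid droplet protein of brown fat, changed by -2.08 and Cox8b by -1.82, whereas Adrb3 was higher by 0.98. The largest fall was that of Pck1, the gluconeogenic and glyceroneogenic enzyme, 8.64-fold (6.58 ± 0.115 against 9.69 ± 0.105, change -3.11, SE 0.0758). Mb, which encodes the heme protein myoglobin, changed by -2.95, the glutathione peroxidase gene Gpx3 by -2.36, Depp1 by -2.07 and Pltp by -1.93.

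Targets of NRF2 and BACH1, transcription factors of the oxidative stress and heme response, were higher with SA: 16 of 17 with none lower (median 0.93, adjusted p = 2.36e-17). Nqo1 rose by 1.51 (SE 0.057), the glutathione synthesis gene Gclc by 1.07 and the catalase gene Cat by 0.94. The lipocalin gene Lcn2 had the largest rise, 4.88-fold (change 2.29, SE 0.0766), and the carbonyl reductase gene Cbr3 rose by 2.07 and Hsd11b1 by 1.47. Gsta3 (2.24) and Ces1f (1.57) belong to families with close paralogs, so their values may hold reads of relatives. The p53 target list had 9 of 12 genes higher and none lower (median 0.27, adjusted p = 2.95e-05), with Cdkn1a at 0.53, Mdm2 at 0.52 and Aen at 0.44.

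BCAA catabolism genes split with SA, 12 of 33 lower and 5 higher (6 higher and 12 lower when adjusted over the list alone), and the list as a whole did not pass its test (median -0.04, adjusted p = 0.135). Pcca, a subunit of propionyl-CoA carboxylase, changed by -0.59 (SE 0.0301), the kinase gene Bckdk by -0.44, Bckdhb by -0.36 and Mccc2 by -0.35. Fatty acid oxidation genes were lower, 13 of 18 with none higher (median -0.24), with Hadhb at -0.82 and the carnitine carrier gene Slc25a20 at -0.81. Complex I genes were lower, 26 of 36 with none higher (median -0.25). These 2 lists had adjusted p of 4.18e-07 and 2.12e-09, and adjusted p = 0.127 and 0.138 with an estimated correlation. Extracellular matrix genes were lower in 13 of 18 cases (median -0.41, adjusted p = 9.86e-08, and adjusted p = 0.127 with an estimated correlation), Col1a1 by -1.02 and Eln by -1.01.

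Markers of other cells and states moved with SA as well. Macrophage markers were lower in 9 of 13 cases and higher in 1 (median -0.32, adjusted p = 0.00219, and adjusted p = 0.226 with an estimated correlation), Mrc1 by -0.97. Interferon response genes were lower, 9 of 11 (median -0.74, adjusted p = 8.17e-05, and adjusted p = 0.234 with an estimated correlation), Irf7 by -1.11. Circadian clock genes were higher, 11 of 14 (median 0.23, adjusted p = 0.000177, and adjusted p = 0.0697 with an estimated correlation), Arntl by 0.57 and Per1 by 0.53. General adipocyte genes had 10 of 22 higher and 4 lower, with a median of 0.11, a mean of -0.04 and an adjusted p of 0.114. Of 12799 genes limma called 5298, 2556 higher and 2742 lower, with 19 up and 70 down at least 2-fold. The share of higher genes was 48.2%, and it was 56.6% after median centring and 52.9% after quantile normalization.

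Heme-arginate alone lowered Alas1 (12.10 ± 0.08 against 12.42 ± 0.0596, change -0.33, SE 0.0469, n = 4, limma adjusted p = 0.000243) while Ucp1 did not change by the test (-0.04, 95% CI -0.276 to 0.204, adjusted p = 0.894). Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, rose 4.57-fold (15.84 ± 0.141 against 13.65 ± 0.167, change 2.19, SE 0.0783). The iron exporter gene Slc40a1 rose by 1.00, the heme transporter gene Slc48a1 by 0.49 and the ferritin gene Fth1 by 0.47, while the transferrin receptor gene Tfrc fell by 1.13 (SE 0.106). Marco, a macrophage scavenger receptor gene, rose most (2.42, SE 0.0956), with Lyz2 (1.19), whose reads may be shared with its paralog Lyz1, Clec4n (1.12) and the metallothionein gene Mt2 (0.88). The leptin gene Lep had the largest fall (-1.22, SE 0.0722), followed among others by Acta1 (-0.77) and Pck1 (-0.74).

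NRF2 and BACH1 targets were higher with HA in 14 of 17 cases with none lower (median 0.25, adjusted p = 3.72e-19), Gclm by 0.67 and Gclc by 0.46. The integrated stress response list had 10 of 26 genes higher and 1 lower (14 and 1 when adjusted over the list alone), with a median of 0.13 and an adjusted p of 1.44e-06. Chac1 (0.32), Trib3 (0.27) and Atf4 (0.22), a central transcription factor of this response, were among them. BCAA catabolism genes had 3 of 33 lower and none higher (0 higher and 5 lower when adjusted over the list alone; median -0.03, adjusted p = 0.108), namely Acadsb (-0.15), Oxct1 (-0.22) and Mcee (-0.24). Macrophage markers had 2 of 13 higher and 1 lower (median 0.12, adjusted p = 0.00576, and adjusted p = 0.31 with an estimated correlation). Thermogenic genes had 1 of 20 higher and 4 lower (median -0.03, adjusted p = 0.281), with Cidea at 0.72 and Adrb3 at -0.42. Limma called 1148 of 12799 genes, 625 higher and 523 lower, with 4 up and 2 down at least 2-fold. The share of higher genes was 54.4%, and it was 61.9% after median centring, 52.3% after quantile normalization and 49.4% without Vehicle replicate 4. The count fell to 694 without HA replicate 2 or without Vehicle replicate 1.

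Heme-arginate added to SA brought Alas1 from 13.72 ± 0.0691 to 12.48 ± 0.0703 (HASA against SA, change -1.24, SE 0.0469, n = 4, limma adjusted p = 2.31e-11) while Ucp1 had no change that passed (0.02, 95% CI -0.221 to 0.259, adjusted p = 0.922). Ucp1 values in SA and HASA had SDs of 0.0261 and 0.0454 against 0.235 in Vehicle, so the low values hardly varied, and a change of Ucp1 with heme in inhibited cells is not excluded. Hmox1 rose by 1.84, Marco by 2.43, Slc40a1 by 0.82, Cyp1b1 by 1.10, the cystine transporter gene Slc7a11 by 1.08 and Igfbp5 by 1.04. Acta1 (-1.29), Timp4 (-0.91), Coro6 (-0.85) and Aspg (-0.84) had the largest falls besides Alas1. The thermogenic list had 9 of 20 genes lower and none higher (median -0.18, adjusted p = 0.00123), with Ppargc1a at -0.44. BCAA catabolism genes had 8 of 33 lower and 3 higher (3 higher and 15 lower when adjusted over the list alone; median -0.09), with Bckdhb at -0.26, Hibch at -0.23 and Mmab at 0.17. That list had an adjusted p of 0.00683, and adjusted p = 0.34 with an estimated correlation.

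Other gene groups differed between HASA and SA. Macrophage markers were higher in 12 of 13 cases (median 0.55, adjusted p = 2.98e-11), C1qb by 0.72 and C1qa by 0.70. Extracellular matrix genes were higher in 16 of 18 (median 0.35, adjusted p = 3.88e-13, and adjusted p = 0.0624 with an estimated correlation), Col6a2 by 0.60 and Fbn1 by 0.57. NRF2 and BACH1 targets were higher still in 10 of 17 (median 0.17, adjusted p = 1.84e-05, and adjusted p = 0.069 with an estimated correlation), Nqo1 by 0.68. Circadian clock genes had 10 of 14 lower and 1 higher (median -0.23, adjusted p = 1.42e-05), Per3 by -0.50. Limma called 3157 genes, 1583 higher and 1574 lower, with 7 up and 2 down at least 2-fold.

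How far heme moved the genes that SA had changed was measured by choosing genes with 2 SA libraries and measuring the return with the other 2, for all 6 choices. Among genes lower with SA by at least 0.5 (393 to 422 per choice, median -0.71), 63.0% moved back with heme (60.5 to 67.1%), by a median of 0.08. Genes higher by at least 0.5 (204 to 212, median 0.64) moved back in 51.0% of cases (42.8 to 54.3%), by a median of -0.0018. Over all genes lower with SA (2076 to 2235) 56.5% moved back (median 0.02), and over all genes higher (1879 to 2046) 60.6% (median -0.04). The median change of all genes from the other 2 SA libraries to HASA was -0.0047 to -0.0027 over the choices. How the chosen genes moved with HA against Vehicle was not measured. A return from inhibition is therefore not told apart from an effect that heme has without SA. These shares are descriptions across genes that are not independent, and no test was made of them.

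**Figure D2:**
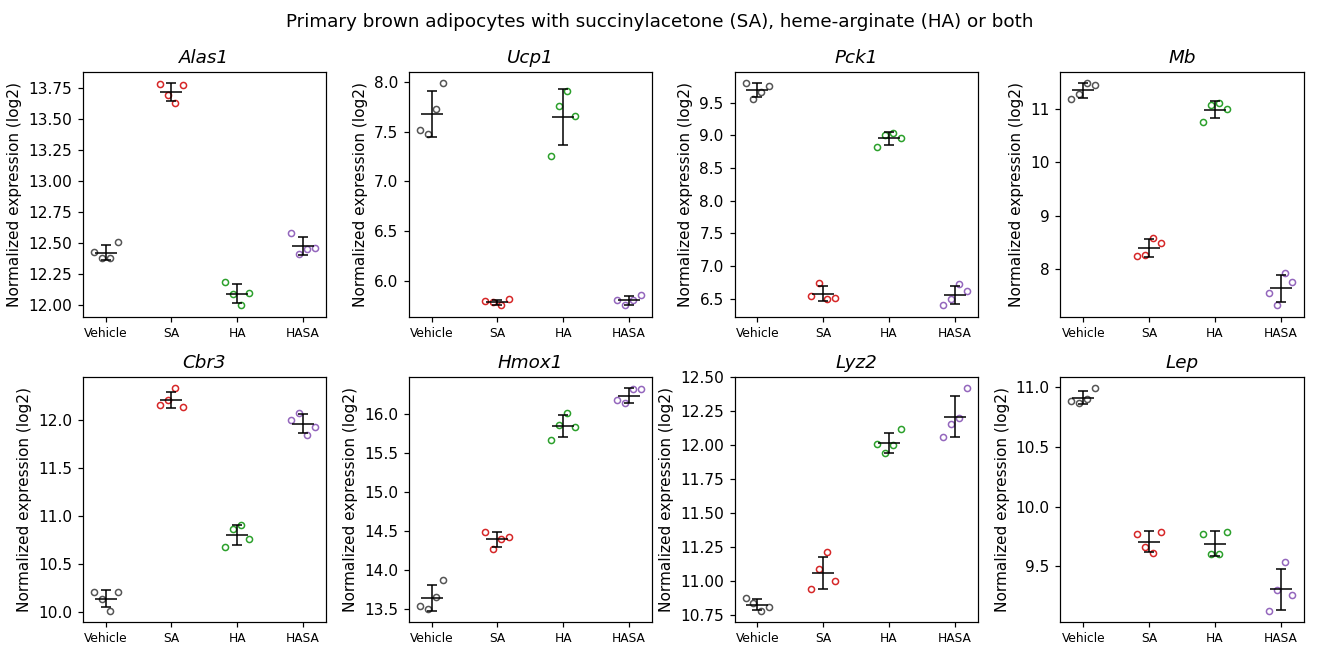
Log2 values of Alas1, Ucp1, Pck1, Mb, Cbr3, Hmox1, Lyz2 and Lep in pBAT adipocytes given Vehicle, SA, HA or both (HASA). Points are libraries and bars are mean ± SD (n = 4).

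With both compounds Alas1 was near Vehicle (change 0.05, SE 0.0469, 95% CI -0.0483 to 0.149, limma adjusted p = 0.41), while Ucp1 was 3.68-fold lower (change -1.88, SE 0.114, adjusted p = 4.18e-10). Mb (-3.71), Pck1 (-3.13), Gpx3 (-2.79) and Depp1 (-2.71) had the largest falls, and Lcn2 (2.93), Marco (2.88), Hmox1 (2.58) and Nqo1 (2.19) the largest rises. BCAA catabolism genes had 16 of 33 lower and 2 higher (2 higher and 18 lower when adjusted over the list alone; median -0.13, adjusted p = 0.00192, and adjusted p = 0.234 with an estimated correlation), with Bckdhb at -0.61 and Dbt at -0.50. Complex I genes were lower in 33 of 36 (median -0.33, adjusted p = 4.63e-14, and adjusted p = 0.0893 with an estimated correlation), and thermogenic genes in 16 of 20 with 1 higher (median -0.48, adjusted p = 5.1e-08). Limma called 5616 genes, 2672 higher and 2944 lower (47.6% higher, but 56.7% after median centring and 51.4% after quantile normalization).

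Against HA alone, adding SA raised Alas1 by 0.38 (SE 0.0469, n = 4, limma adjusted p = 4.2e-06) and lowered Ucp1 3.59-fold (change -1.84, SE 0.114). Mb (-3.35), Cidea (-2.96) and Gpx3 (-2.88) fell most, and Lcn2 rose by 2.51. BCAA catabolism genes had 16 of 33 lower and 7 higher (7 higher and 19 lower when adjusted over the list alone; median -0.13, adjusted p = 0.0177, and adjusted p = 0.314 with an estimated correlation). Thermogenic genes had 16 of 20 lower and 2 higher (median -0.50, adjusted p = 2.31e-07), and NRF2 and BACH1 targets 16 of 17 higher (median 0.74, adjusted p = 3.18e-15). Limma called 5471 genes, 2610 higher and 2861 lower (47.7% higher, but 53.7% after median centring and 50.7% after quantile normalization).

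Whether heme acted differently in inhibited cells was tested as the interaction of SA and HA. Alas1 had an interaction of -0.91 (SE 0.0663, n = 4, limma adjusted p = 1.16e-06), its fall with heme being -0.33 without SA and -1.24 with it. Ucp1 had none that passed (0.06, 95% CI -0.284 to 0.395, adjusted p = 0.878), with the same limit from its low values in SA and HASA. B3galt2 (1.26), Lep (0.82), Tfrc (0.77) and Mrc1 (0.75) had positive terms, and Cbr3 (-0.91), Cidea (-0.88) and the stress response gene Ddit3 (-0.53) negative ones. Extracellular matrix genes had 12 of 18 positive terms (median 0.31, adjusted p = 2.84e-11, and adjusted p = 0.0693 with an estimated correlation), and complex I genes 12 of 36 negative (median -0.17, adjusted p = 2.43e-11, and adjusted p = 0.0874 with an estimated correlation). BCAA catabolism genes had 1 of each sign among 33 (median -0.04, adjusted p = 0.132). Limma called 982 genes, 497 positive and 485 negative (50.6% positive, but 48.9% after median centring and 56.7% after quantile normalization), and 1 of them had a term of at least 2-fold.

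**Figure D3:**
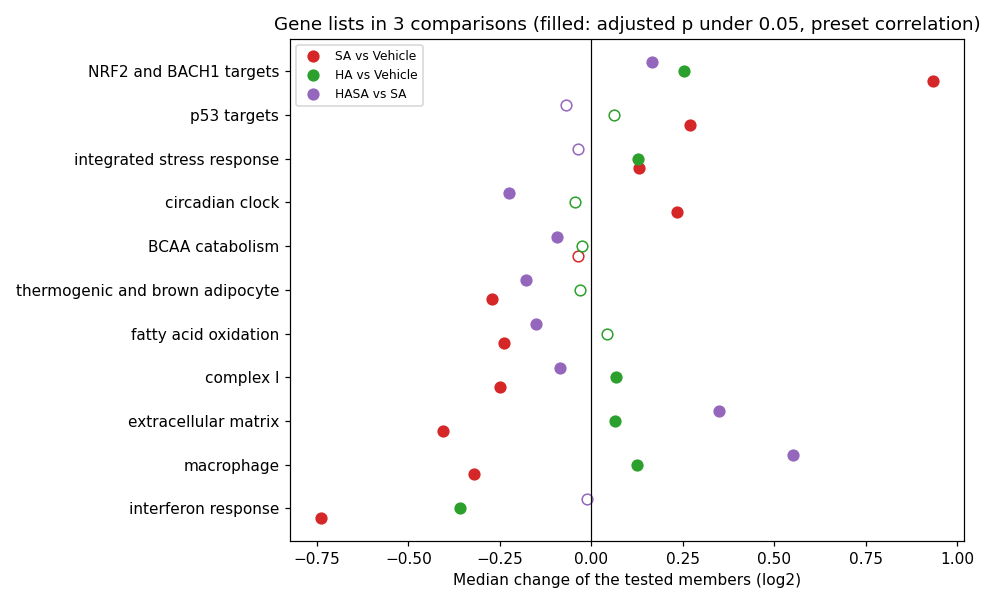
Median log2 change of 11 gene lists for SA against Vehicle, HA against Vehicle and HASA against SA (n = 4 per group). Filled points have an adjusted p under 0.05 with the preset correlation between genes. Of the 34 lists tested, that correlation called 17, 16 and 14 in these comparisons, and the estimated one called 3 in each.

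Alas1 was lower in all 4 BAKO brown fat libraries (10.15, 10.18, 10.45 and 10.61 in BAKO 1, 2, 3 and 5) than in all 4 WT libraries (12.79, 12.90, 12.73 and 12.97 in WT 1, 3, 4 and 5). The change was -2.50 (10.35 ± 0.223 against 12.85 ± 0.111, SE 0.113, n = 4, limma adjusted p = 1.34e-05), a 5.66-fold fall. No other heme synthesis gene passed: Alas2, the erythroid form, was at -0.45 (adjusted p = 0.722), Fech at -0.15 (0.776), Uros at 0.11 (0.701) and Urod at -0.10 (0.799). Since the heme synthesis list holds the deleted gene, its test as a list is not given for BAKO. Ucp1 was at 16.47 ± 0.383 in BAKO and 16.75 ± 0.111 in WT (change -0.28, 95% CI -0.686 to 0.126, adjusted p = 0.7). The limma count was 15 of 13497 genes, 7 higher and 8 lower, with 1173 at an unadjusted p under 0.05. Quantile normalization gave 14 genes, 57.1% of them higher against 46.7%.

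Besides Alas1, the carbonyl reductase gene Cbr3 (1.30, SE 0.148, adjusted p = 0.0167) and the glutathione transferase gene Gsta3 (1.53, SE 0.177, adjusted p = 0.0167) were called in BAKO. Gsta3 has close paralogs, and its reads may be shared. The sarcomere gene Actn2 (1.25), the aspartate transaminase gene Got1 (1.07), Nupr1 (0.64) and the matrix gene Tnc (0.64) were also higher. Mmd2 (-1.01, SE 0.106, adjusted p = 0.0167), the lactate receptor gene Hcar1 (-0.93), Grk3 (-0.58), Acp5 (-0.54) and Gnao1 (-0.50) were lower. The calls besides Alas1 changed with single libraries: Alas1 alone was called without BAKO 1, BAKO 3, WT 1, WT 3 or WT 4 (1 gene each), 7 genes were called without BAKO 2, 13 without BAKO 5 and 16 without WT 5.

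Integrated stress response genes had a median change of 0.49 in BAKO, with 1 of 25 called higher over all genes and 11 higher and 1 lower when adjusted over the list alone (n = 4). Nupr1 was the called one, while Trib3 (1.12, adjusted p = 0.0596), Phgdh (0.71, 0.0839) and Mthfd2 (1.2, 0.196) did not pass. The list had an adjusted p of 3.21e-11, and adjusted p = 0.299 with an estimated correlation. General adipocyte genes had a median of -0.26 with none of 22 called (0 higher and 6 lower when adjusted over the list alone; adjusted p = 1.52e-07, and adjusted p = 0.313 with an estimated correlation), with Cfd at -0.86 (adjusted p = 0.268) and Plin1 at -0.37 (0.279). Thermogenic genes had a median of -0.21 with none of 21 called (0 higher and 1 lower over the list alone; adjusted p = 0.000115, and adjusted p = 0.58 with an estimated correlation). Without BAKO 3 and BAKO 5 together, an alternative chosen after seeing the data, the thermogenic list had an adjusted p of 0.194.

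BCAA catabolism genes in BAKO had a median of -0.13 with none of 33 called, over all genes or over the list alone. Ivd was at -0.24 (adjusted p = 0.504) and Bckdk at -0.18 (0.556). The list had an adjusted p of 0.012, and adjusted p = 0.786 with an estimated correlation. It lost its call without BAKO 5 (adjusted p = 0.751) or WT 1 (adjusted p = 0.191). The libraries differed in muscle and immune markers: the mean of 15 skeletal muscle genes stood 4.71 above the average of all libraries in BAKO 3 and 1.48 above it in WT 4, against -1.32 to -0.03 in the other 6. Macrophage markers had a median of 0.36 with none of 15 called (adjusted p = 0.00171, and adjusted p = 0.7 with an estimated correlation), and lost that call without BAKO 5 (adjusted p = 0.0811) or WT 1 (0.0572).

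**Figure D4:**
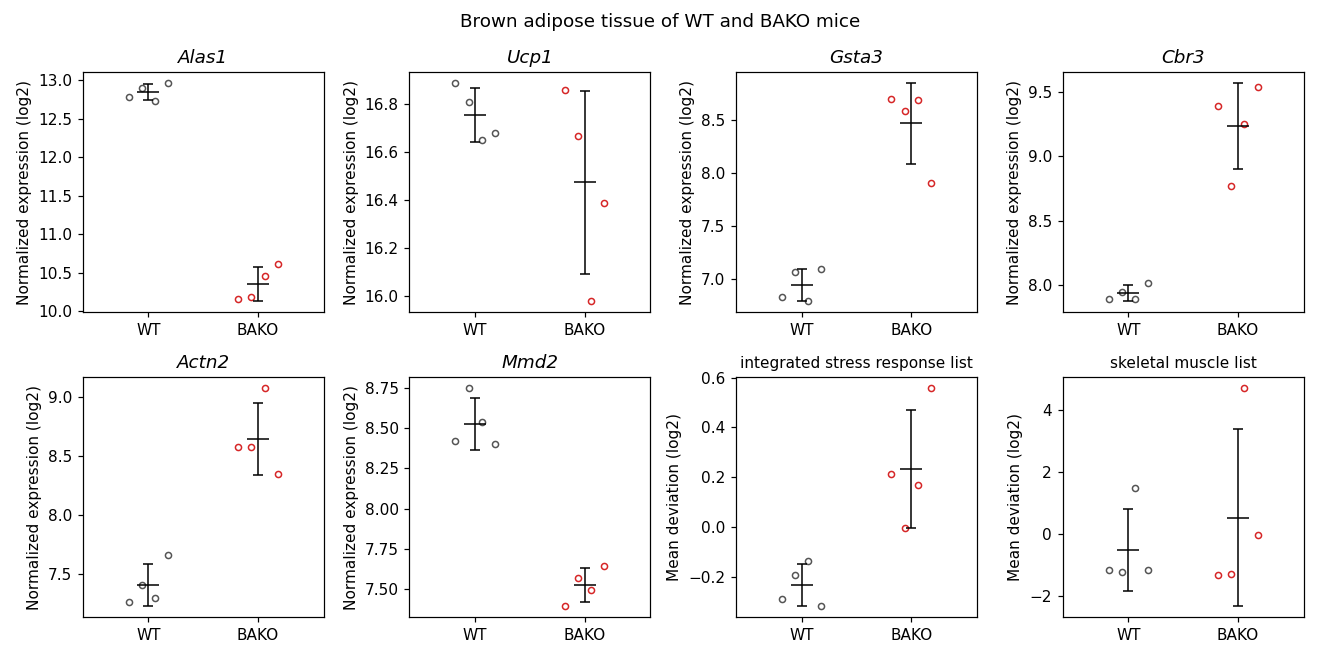
Alas1, Ucp1, Gsta3, Cbr3, Actn2, Mmd2 and the means of the integrated stress response and skeletal muscle lists in each brown fat library of WT and BAKO mice. Points are animals and bars are mean ± SD (n = 4).

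SA in culture and loss of Alas1 in tissue were set against each other over 12149 genes tested in both experiments, which share no library. Their log2 changes had a Pearson correlation of -0.0312 and a Spearman correlation of -0.0341 across genes, which are not independent replicates. Alas1 itself went opposite ways, as did Cd1d1, Gnao1, Got1 and Tnc. Cbr3, Gsta3, Nupr1 and Cxcl10 were called higher in both (4 genes, 1.21 expected by chance) and Acp5, Grk3, Hcar2 and Mmd2 lower in both (4 genes, 1.70 expected). Over genes of at least 10 CPM in both, 2 were called higher in both (0.948 expected) and 1 lower (0.841 expected). Cxcl10, Cd1d1 and Hcar2 were named after their values were seen. The 200 genes with the largest rises in SA had a higher direction in BAKO that did not pass (camera p = 0.0728, and p = 0.307 with an estimated correlation). Of these, 31 were higher in BAKO at an unadjusted p under 0.05, against 522 of all 12149 genes. Over genes of at least 10 CPM the counts were 19 of 200 and 246 of 7464. The 200 with the largest falls had a higher direction in BAKO (camera p = 0.00372), with p = 0.281 with an estimated correlation and p = 0.15 over genes of at least 10 CPM. Of these, 9 were lower in BAKO at an unadjusted p under 0.05, against 540 of all genes. Over genes of at least 10 CPM it was 21 of 200, against 405 of 7464. These counts were not tested. Of the genes called lower with SA, 167 were lower in BAKO at an unadjusted p under 0.05, against 115 expected by chance if genes were independent. Of those called higher with SA, 118 were higher in BAKO, against 105 expected.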

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

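The counts of called genes in other splits were planned before the data were examined. The macrophage test of the integrated stress response is recorded as written before too. The choice of that list, however, followed its result, so the test is read here as chosen afterwards. The other tests of this part were chosen after the result was seen. In groups of 4 libraries, a gap test marks a library that lies far from the other 3, and chance marks about 1 in 20 groups. It marked 9 of 198 gene groups (4.55%) and 2 of 60 list groups (3.33%).

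In experiment 2 the marked libraries, with the gap as a share of the group's range, were these. Depp1 lay at 9.71 in HA 4 against a mean of 9.80 in the others (share 0.857). Alad lay at 9.53 in SA 2 against 9.43 (0.896), Urod at 10.68 in SA 3 against 10.50 (0.873), Pltp at 8.90 in SA 3 against 8.97 (0.926) and Clec4n at 6.75 in SA 1 against 6.43 (0.938). Ppox lay at 9.56 in Vehicle 1 against 9.39 (0.872) and Cyp1b1 at 11.38 in Vehicle 4 against 11.64 (0.856). The heme synthesis list mean lay at 0.11 in SA 3 against 0.16 (0.928). In experiment 3 Gsta3 lay at 7.90 in BAKO 5 against 8.66 (0.845), Ppox at 9.76 in WT 1 against 10.00 (0.872), and the skeletal muscle list mean at 1.48 in WT 4 against -1.18 (0.968).

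Some lists went opposite ways in every library of 2 cell types by day 6, and these differences were not tested. They were picked from 108 pairs of cell types looked at over the lists. Mean changes were 1.03 in B9 and -0.13 in pBAT for creatine and calcium cycling. For sterol synthesis they were 0.105 in B9, -0.55 in pBAT and -0.13 in pWAT, and for the integrated stress response 0.94, -0.07 and -0.51. Quantile normalization moved the median of all genes in B9 at day 6 from 0.029 to -0.093. The small B9 rise of sterol synthesis may therefore depend on the scaling. Preadipocyte and fibroblast genes changed by -0.25 in B9, -0.91 in pBAT and 0.25 in pWAT, with pWAT opposite to both. The interaction of SA and HA, tested directly, had 982 called genes.

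Other splits of the same libraries were counted for each comparison. In experiment 1 only 10 splits exist, too few for a share under 0.05, and 1 of them, the real one, was as large in each of the 9 comparisons: the highest other count was 1 at day 2 in B9 and pWAT and 0 elsewhere. In experiment 2, 1 of 35 splits was as large as the real one in each pair of treatments, with the highest other count at 1 for SA, 2 for HA, 1 for HASA against Vehicle, 1 for HASA against SA and 0 for HASA against HA. For BAKO against WT 1 of 35 was as large as the real 15 and the highest other count was 1. In all these comparisons each other split mixes the groups, so any real difference goes into the residual and lowers its count. The gap between the real and the other counts is therefore no measure of how many calls chance would give. Only the rank of the real split can be read, and 1 of 35 is the smallest share possible. For the interaction the 100 splits were the real one and a random draw of the others. Of these, 3 were as large, the highest other count being 1482. The 2 other splits as large keep the HASA and SA libraries apart, so the effect of heme in inhibited cells is still in them. Further splits that left HASA and SA, or HA and Vehicle, unmixed called 804, 514 and 252 genes. Splits that mixed both pairs called 0 or 1, but mixing puts the effect of heme into the residual. The share of 3 in 100 therefore cannot tell whether chance gave the count.

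The mean of the integrated stress response list was 0.47 higher in BAKO than in WT, with 1 of 25 genes called and an adjusted p of 0.299 with an estimated correlation. If libraries BAKO 3 and BAKO 5 made the difference it would be under 1 SD of the WT libraries (0.085) without them, and it was 0.337, which speaks against that. If macrophage content made it, the interval with the macrophage list as a covariate would reach 0, and the difference was 0.351 (SE 0.109, 95% CI 0.072 to 0.63). Other splits gave at most 0.402, so 1 of 35 was as large as the real one (exact permutation p = 0.0286, the smallest possible), but adjusted over the 36 lists that p is 0.343, and the general adipocyte list was equally apart. The difference was smaller in both of these checks, so a part played by BAKO 3 and BAKO 5 or by macrophage content is not excluded. Muscle tissue was not tested for this list. Chance among the lists and loss of Alas1 are left open too, the list having been picked after its result was seen.

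Actn2, a sarcomere gene, was higher in BAKO, and muscle tissue in the dissected fat could raise it. With the skeletal muscle list mean as a covariate its change was 1.18 (SE 0.148, 95% CI 0.846 to 1.51, adjusted p = 0.0366), so that list does not account for it.

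Marco and Lyz2 were higher with HA, and 12 of 13 macrophage list genes were higher in HASA against SA. A macrophage share large enough to account for Lyz2 (1.19) would raise the other macrophage markers about as much. The median of the 12 others was 0.108 (SD 0.158), which speaks against a share that large. Lyz2 was picked for its large rise, so a smaller gain in macrophage share with HA is not excluded. In HASA against SA the macrophage list had a median of 0.55 (SD 0.26) and its 12 genes other than Lyz2 one of 0.525, so a larger macrophage share is not excluded there. A lower share of adipocytes would raise other cell types alike. The smooth muscle and pericyte list had a median of -0.053, the endothelial list (4 tested genes) 0.117 and the general adipocyte list 0.104. These values speak against a rise of all other cell types alike. Extracellular matrix genes, however, were mostly higher in HASA against SA, so a shift in some cell types is not excluded. Whether heme changed the number of macrophages or their genes is left open.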

How the results depend on the processing

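Median centring, quantile normalization, the fit without the trend, the stricter filter, the covariates and the fit without BAKO 3 and BAKO 5 were chosen after the results were seen. List calls depended most on the setting: with the estimated correlation 226 of 298 were lost and 72 kept, the losses including all 20 in BAKO against WT and all 23 in the interaction. Named genes mostly kept their direction and their side of the threshold, and the counts of called genes stayed within 1.5 times their value except for HA against Vehicle and BAKO against WT. With each library left out in turn, the count for HA against Vehicle ranged from 694 to 1108 and that for BAKO against WT from 1 to 16 (1 without BAKO 1, BAKO 3, WT 1, WT 3 or WT 4, and 7 without BAKO 2), with fewer libraries in the fit. Other such ranges were 9506 to 9599 for B9, 9697 to 9872 for pBAT and 8721 to 9229 for pWAT at day 6, 4758 to 4948 for SA, and 704 to 1061 for the interaction. BAKO against WT gave 4 genes without BAKO 3 and BAKO 5 together (fewer libraries), 8 with the skeletal muscle covariate, 12 with the macrophage covariate or without the filter, 13 without the trend, and 14 or 15 with the other scalings and the stricter filter; where libraries were kept, the cause was not tested.

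Taking the replicate number in the library name as a replicate block, a check of pairing, gave 3 genes for BAKO against WT, 5276 for SA, 1112 for HA, 923 for the interaction, and 9478, 9907 and 9154 at day 6 in B9, pBAT and pWAT. The number in the sample title as a block gave 9831, 10161 and 9269 at day 6 in B9, pBAT and pWAT. Libraries with the same number in their names showed no steady pairing: the correlations of their residuals were -0.0758 to 0.121, -0.176 to 0.21 and -0.0201 to 0.48 in experiments 1, 2 and 3. In experiment 1 such correlations were not taken by title number. Not every pair was over 0.1 in any of them. Libraries correlating best with their own number ran from 0 of 4 (HA against Vehicle) to 2 of 2 (B9 day 6). In BAKO against WT they were 2 of 3. With so few pairs, pairing is not excluded. The cause was not tested.

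Quantile normalization turned Gapdh with HA to -0.063 and its interaction to 0.063, and moved the median of all genes to -0.104 in pBAT day 4, -0.108 in pWAT day 4 and -0.124 in pWAT day 6. The cause was not tested. In BAKO against WT the skeletal muscle list turned to lower without BAKO 3 (adjusted p = 0.0893), and over the libraries left out in turn its adjusted p ran from 0.000361 to 0.191. Without BAKO 3 and BAKO 5 it turned to lower as well (0.0105), and the direction also turned for BCAA catabolism (0.714), complex I (0.0367), complexes II and III with cytochrome c (0.588) and endothelial markers (0.856); fewer libraries were in these fits.

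In the heme add-back all 4 SA libraries used for both steps gave 66.4% moved back for genes higher with SA and 59.8% for genes lower, a choice that by construction counts the noise of the shared libraries as return. For genes higher by at least 0.5, SA 1 and SA 2 as choosers gave 47.6% and SA 1 and SA 4 gave 42.8%; the cause was not tested. The correlation of SA and BAKO changes was -0.00888 over genes of at least 10 CPM.

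Of single genes named, 8452 results stayed the same with a library left out, 211 lost and 33 gained a call. The planned DESeq2 size factors and DESeq2 test were not run, since they need counts, and the 4 comparisons across cell types were not run. Depth cannot be read from the values, so what it limits is unknown beyond the low genes, whose changes are understated.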

Other observations

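The lists described in this part were fixed before the values, and the choice to describe them here was made after their results were seen. With SA in experiment 2, 4 of 16 iron handling genes were higher and 5 lower (median -0.09, limma adjusted p = 0.456), among them the iron importer gene Slc11a2 (-1.03) and Ftl1 (0.72). Of 20 heme transport, breakdown and sensing genes 9 were higher and 3 lower (median -0.0031, mean 0.18, adjusted p = 0.034, and adjusted p = 0.127 with an estimated correlation). The biliverdin reductase gene Blvrb (0.89), the heme-responsive nuclear receptor gene Nr1d1 (0.69) and Pgrmc1 (0.65) were higher and Tmem14c was lower (-0.44). With HA 3 of 16 iron handling genes were higher and 1 lower (median 0.05, adjusted p = 0.108), Ftl1 by 0.41. Of the 20 heme transport, breakdown and sensing genes 5 were higher and none lower (median 0.02, adjusted p = 0.00374), Blvrb by 0.35.

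In B9 at day 6 of differentiation 20 of 26 integrated stress response genes were higher and 2 lower (median 0.69, limma adjusted p = 0.000449, and adjusted p = 0.118 with an estimated correlation), among them Fgf21 (3.57) and Ddit3 (2.38). In pWAT 7 of 26 were higher and 15 lower (median -0.56, adjusted p = 0.0291, and adjusted p = 0.387 with an estimated correlation), with Chac1 at -2.58. The cell types were not tested against each other.

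Mitochondrially encoded genes made up 2.89 to 11.4% of the summed linear values in cultures and 27.1 to 30.1% in brown fat libraries. Libraries of cultures and brown fat were made by different providers and normalized separately. This contrast was therefore not tested, and tissue and library method cannot be told apart in it.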
